A study of Homo sapiens with 6 samples.

How the data were processed

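RNA was taken from MDA-LM2 cells 48 h after transfection with siRNAs and turned into libraries with a stranded total RNA kit for low input, per the labels' protocols. The 6 libraries fall into 3 groups by the knockdown named in their labels, with 2 siCtrl, 3 siSNRPA1 and 1 siSNRPB library. The labels number replicates but do not say whether they came from separate cultures, and the series design names 3 siRNAs against SNRPA1 without tying each to a library. It names 2 siRNAs against SNRPB, where 1 library is listed, and in 1 place SNRPB2; SNRPB is used here, as in the labels. The submitters' processing notes name STAR 2.7 and the hg38 build, with no role or order. The column names are those of MISO, a program that estimates the inclusion of alternative exons; its version and settings, and how the libraries of a group were combined, are not given in the sources used here.

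For each group the authors deposited 1 summary of skipped-exon events. The inclusion level is a fraction from 0 to 1, per the file headers the posterior mean, which the authors rounded to 2 decimals. Per the file headers each event also has the bounds of an interval around that level, whose width is not stated, and reads in classes that fit the inclusion isoform only, the exclusion isoform only, both or neither. Every event had at least 20 reads in all, reads that fit neither isoform included. In 2 comparison files, siSNRPA1 with siCtrl and siSNRPB with siCtrl, the authors deposited a difference in inclusion, a score from -1 to 1, and a Bayes factor, a ratio of the evidence for a difference to that for none. The deposited differences were checked to equal the difference of the summaries in 44653 of 44653 and 38112 of 38112 events. The number of columns of per-sample values left unused was 0.

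Coordinates are those of the files, on hg38 and counted from 1. Gene names and places within genes came from GENCODE 29, whose exons matched the skipped exon exactly for 95.7% of 47986 events, and some symbols are those of that release. Exon GC content was computed from annotated transcripts, and that of introns was not computed, because no genome sequence was used here. Where several events shared a skipped exon, the one with the most informative reads over the 3 pools was kept, which left 40658 exons. Forms of an exon that differ in start or end were kept as separate exons. Informative reads are those that fit only inclusion or only exclusion. Such reads are not independent molecules, since no molecular identifiers are described, so every interval and test covers counting error only. Neighbouring cassette exons can share exclusion reads, and genes with near-identical copies, such as SMN1, U2AF1, WASHC2C and the ribosomal protein genes, are uncertain because their reads can be split between copies. The strand setting of the counting is not given in the sources used here, so exons that overlap a gene on the other strand are uncertain too. Among the named genes these are EME1, SEPT2, CDK2, ITGA6, RPL17, SNAP23 and FANCI, and they made up 95 of the passing exons in siSNRPA1, 71 in siSNRPB and 68 between the knockdowns.

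An exon was tested with at least 20 informative reads in each pool and at least 5 inclusion and 5 exclusion reads over both. The test was a two-sided Fisher's exact test on these reads with Benjamini-Hochberg adjustment over the tested exons. An exon passed at an adjusted p under 0.05 with a difference in the authors' inclusion level of at least 0.1 in the direction of the read shares. "Fell", "rose" and "passed" refer to this rule. The inclusion level also draws on reads in the flanking exons, so it can differ from the share of inclusion reads. Intervals of read shares are 95% Wilson intervals. Python 3.11.15 was used with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3.

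The procedure was tested on simulated data drawn from the observed read shares and depths, with inclusion as a read share and changes in the form of falls. For siSNRPA1 against siCtrl, 20 pairs of unchanged pools over 6459 exons gave a mean of 0 calls, and of exons changed by 0.2 and 0.4 the test recovered 38% and 88%. For siSNRPB against siCtrl the mean was 0 calls over 4244 exons, and 48% and 81% were recovered. For siSNRPA1 against siSNRPB the mean was 0.1 calls over 5082 exons, with 40% and 83% recovered. A change of 0.2 was thus often missed at these depths.

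Named exons followed a rule set before the data were examined. For each knockdown against siCtrl they were the 8 largest rises and the 8 largest falls among passing exons with at least 50 informative reads in both pools, 1 per gene. To these came up to 3 passing exons of each gene list with the largest difference, and up to 3 exons of SNRPA1, SNRPB, PLEC and ERRFI1. Between the knockdowns they were the 5 largest differences each way. The exon of 1 gene that this rule names is not reported here. The 13 gene lists were fixed at the same time and matched through gene identifiers or symbols. List medians, the percent of a list that passed and the features of passing exons are given as percentiles among 10000 random sets of tested exons of the same size, matched on deciles of informative reads. They describe these pools and are not p-values. The sets were drawn exon by exon, without regard to exons that share a gene, so the percentiles can be too extreme. Target gene reads are those that fit inclusion, exclusion or both over a gene's skipped-exon events, per 1000000 such reads of the pool.

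Alternatives changed the read minimum (10 and 50), the difference (0.05 and 0.2), the test (the authors' Bayes factor of at least 10, or the usual MISO filter), the choice of events, the measure of inclusion, the number of reads (divided by 2) and the depth (thinned to the smallest pool). Subtraction of unspliced reads and the use of 1 exon per gene were added after the data were seen. The subtraction was run with inclusion as a read share. Leaving out libraries and a paired analysis were not run, because each group has 1 value per event. Gene expression was not analysed here beyond the reads of skipped-exon events.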

Results

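Skipped-exon usage was measured by RNA sequencing in MDA-LM2 cells, a lung-metastatic derivative of the MDA-MB-231 breast cancer line, 48 h after transfection with small interfering RNAs. The targets were SNRPA1, the U2 A' protein of the U2 small nuclear ribonucleoprotein (snRNP), which recognises the branch point of introns, and SNRPB, which encodes the SmB/B' proteins of the ring shared by the spliceosomal snRNPs. The labels list 2 libraries with control siRNA (siCtrl), 3 with siSNRPA1 and 1 with siSNRPB. For each group there is 1 set of inclusion levels, so the libraries of a group form a pool and no value here has a replicate or a standard deviation. The siCtrl pool held 46252 annotated skipped-exon events with 5707839 informative reads, meaning reads that fit only the inclusion or only the exclusion of the exon. The siSNRPA1 pool held 46294 events with 7831446 informative reads, and the siSNRPB pool 38460 events with 3396043. The median event had 16, 20 and 13 informative reads in the siCtrl, siSNRPA1 and siSNRPB pools. Reads that fit neither isoform, intronic reads among them, made up a median of 79.9%, 78.1% and 68.8% of the reads of an event in the same order.

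Both targets were low in the pools named for them. Reads that fit an isoform of the 4 annotated skipped-exon events of SNRPA1 came to 118 per 1000000 such reads of the pool in siCtrl, 21.9 in siSNRPA1 and 272 in siSNRPB. The siSNRPA1 value was 18.5% of that in siCtrl, the lowest ratio among 7529 genes with at least 200 such reads in at least 1 pool. With all annotated events in place of 1 per skipped exon, 1 of 7655 genes had a lower ratio. Reads over the single event of SNRPB came to 247 per 1000000 in siCtrl, 337 in siSNRPA1 and 30.6 in siSNRPB. The siSNRPB value was 12.4% of that in siCtrl, with 23 of 7529 genes at a lower ratio (43 of 7655 with all annotated events). The labels give knockdowns by quantitative PCR of 86%, 83% and 75% for SNRPA1 (numbered 1 to 3) and 86% for SNRPB, without naming the libraries. SNRPA1 stood at 230% of siCtrl in the siSNRPB pool, and SNRPB at 136% of siCtrl in the siSNRPA1 pool. The 124-nt exon of SNRPB (hg38 chromosome 20, 2467192 to 2467315), partly coding, had inclusion levels of 0.01, 0.00 and 0.01 in siCtrl, siSNRPA1 and siSNRPB and passed in no comparison.

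The first comparison set the siSNRPA1 pool against siCtrl. In the siSNRPA1 pool 827 exons of 684 genes fell in inclusion and 270 exons of 244 genes rose, out of 6459 tested exons. The median fall was 0.21 and the median rise 0.18 on the scale of the inclusion level, which runs from 0 (always skipped) to 1 (always included). Among exons with at least 50 informative reads in both pools, HARS2, the mitochondrial histidyl-tRNA synthetase, fell most. Its 173-nt exon (hg38 chromosome 5, 140696029 to 140696201), partly coding, went from an inclusion level of 0.93 (the authors' interval 0.79 to 1.00) to 0.26 (0.20 to 0.33). Inclusion reads were 61 of 61 informative reads in siCtrl (100%, 95% Wilson interval 94.1 to 100%) and 61 of 118 in siSNRPA1 (51.7%, 42.8 to 60.5%).

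Further large falls were in ACVR1B, an activin receptor kinase, from 0.95 to 0.30, and in RSRP1, an arginine- and serine-rich protein. The RSRP1 exon, which matched no annotated exon, went from 0.67 to 0.10. EME1, a subunit of a structure-specific DNA endonuclease, fell from 0.95 to 0.38, and PPIL3, a cyclophilin-like protein, from 0.80 to 0.24. MSL1, a scaffold of a histone acetyltransferase complex, fell from 0.85 to 0.32. HSPA9, the mitochondrial HSP70 chaperone, fell from 0.99 to 0.48, with 0 exclusion reads beside 496 inclusion reads in siCtrl and 84 beside 577 in siSNRPA1. MRPS18C, a mitochondrial ribosomal protein, fell from 0.89 to 0.39. In all exons described in this paragraph, falls and rises alike, the share of inclusion reads changed less than the inclusion level. In ACVR1B, MSL1 and HSPA9 the share went from 100% in siCtrl to 74.0%, 75.9% and 87.3% in siSNRPA1. The largest rise at that depth was in PCID2, which takes part in mRNA export. Its 2080-nt exon, which matched no annotated exon, went from 0.12 to 0.62. ZSWIM7, a homologous recombination factor, rose from 0.38 to 0.82 at an exon of a noncoding transcript. XYLT2, a xylosyltransferase that starts glycosaminoglycan chains, rose from 0.47 to 0.90. TANC1 rose from 0.56 to 0.97, THADA from 0.56 to 0.91 and SEPT2, a septin, from 0.53 to 0.88 at a 5' UTR exon. DDX39B, an RNA helicase of splicing and mRNA export, rose from 0.39 to 0.74. The share of inclusion reads went from 91.2% in siCtrl to 99.2% in siSNRPA1 for PCID2. For XYLT2 it went from 79.2% to 100%, and for TANC1 from 92.1% to 100%.

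**Figure D1:**
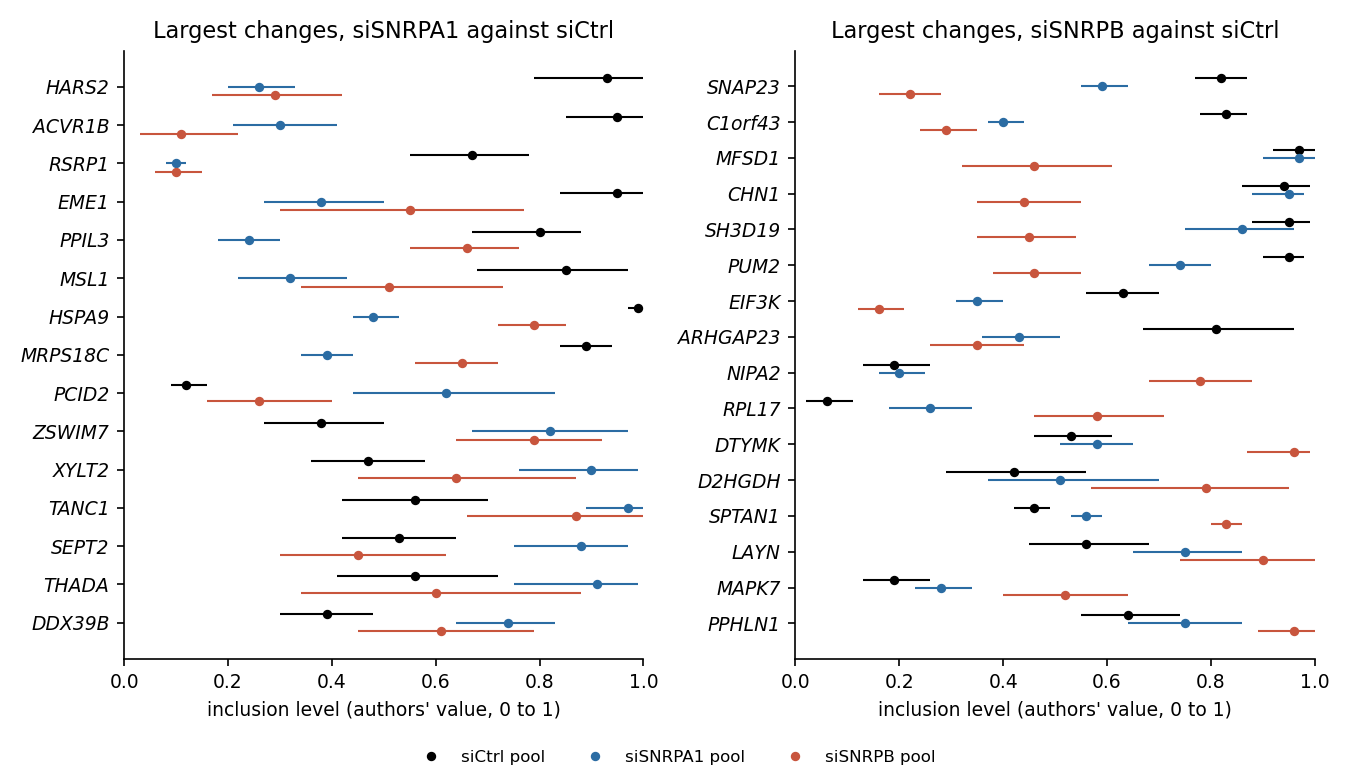
Inclusion level (horizontal axis, 0 to 1, the authors' values) of the exons described in the text with the largest falls (upper lines) and rises (lower lines) among those with at least 50 informative reads in both pools, in siSNRPA1 against siCtrl (left) and siSNRPB against siCtrl (right). Points are the 3 pools and bars the authors' intervals, which hold no spread between libraries; HARS2 lies at 0.93 in siCtrl, 0.26 in siSNRPA1 and 0.29 in siSNRPB, while CHN1 lies at 0.94, 0.95 and 0.44.

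Genes of the splicing machinery were examined as 4 lists. Among the U2 snRNP and its partners, 2 of 18 tested exons fell, 0 rose and 16 did not pass, the 2 being the 205-nt exon of SF1, the branch point binding protein (0.52 to 0.31), and the 37-nt exon of DDX42 (0.99 to 0.84). Adjusted over the list alone the counts were also 2 and 0. Of 35 exons of Sm, LSm and other snRNP proteins, 5 fell and 1 rose, and adjusted over the list alone also 5 and 1. SMN1, needed to assemble Sm rings, fell from 0.74 to 0.33 at its 54-nt exon, TXNL4A from 0.41 to 0.15 and SNRPG from 0.74 to 0.58. SR proteins, their kinases and related genes had 5 falls and 1 rise in 78 exons (5 and 2 adjusted over the list alone), among them RSRP1, SRRM1 (0.61 to 0.24) and PNISR (0.34 to 0.05). The share of this list that passed, 7.69%, lay at the 2.34th percentile of random sets of tested exons of like depth. It was the lowest such percentile, and those of the other lists with enough exons ran from 9.2 to 87.8. Of 94 exons of hnRNPs and other splicing regulators, 11 fell and 3 rose, the same numbers as adjusted over the list alone. MBNL1 fell from 0.91 to 0.58 at a 36-nt exon, CELF2 from 0.89 to 0.64 and RBM41 from 0.63 to 0.34. The share of inclusion reads of MBNL1 went only from 100% in siCtrl to 89.9% in siSNRPA1.

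In genes of the cell cycle and mitosis 16 of 82 tested exons fell and 1 rose, with the same counts adjusted over the list alone. The falls were in 10 genes. NUMA1, a spindle pole protein, fell from 0.83 to 0.25 at a 127-nt exon of a noncoding transcript. CDK2 fell from 0.66 to 0.23 at a 102-nt coding exon and CDK5 from 0.76 to 0.33. The median difference of the list was -0.04, at the 0.385th percentile of random sets. Growth factor and kinase signalling had 17 falls and 3 rises in 104 exons (15 and 3 adjusted over the list alone). Falls were in RICTOR, an mTOR complex subunit (0.65 to 0.22), and CAMK2G (0.94 to 0.58). PTK2, the focal adhesion kinase, fell from 0.70 to 0.30 at a 5' UTR exon. DNA repair genes had 5 falls and 1 rise in 38 exons, also when adjusted over the list alone. FANCA fell from 0.95 to 0.36, and EYA3 from 0.55 to 0.26 at an exon of a noncoding transcript. The 5' UTR exon of RECQL rose from 0.48 to 0.89. Of 119 exons of chromatin regulators 11 fell and 5 rose, again with equal counts adjusted over the list alone. The histone demethylase KDM6A fell from 0.92 to 0.53 and CHD3 from 0.50 to 0.18. SETD5 rose from 0.01 to 0.25 at a 3' UTR exon. Apoptosis genes had 3 falls and 1 rise in 48 exons (3 and 0 adjusted over the list alone). BIRC5, or survivin, fell from 0.54 to 0.34 at an 816-nt exon of a noncoding transcript. AIFM1 fell from 0.15 to 0.02 and CASP8 rose from 0.23 to 0.59.

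Genes with exons known to switch in the epithelial-mesenchymal transition had more rises than falls, 9 and 3 in 75 exons (9 and 4 adjusted over the list alone). PICALM rose from 0.41 to 0.74 at a 24-nt exon, MAP3K7 from 0.19 to 0.46 and ITGA6, an integrin subunit, from 0.36 to 0.63. Genes of the cytoskeleton and cell adhesion had 13 falls and 7 rises in 114 exons, also when adjusted over the list alone. NEXN rose from 0.14 to 0.46 and LIMCH1 fell from 0.77 to 0.45. The median difference of this list was 0, at the 99.1st percentile of random sets, whose middle 95% ran from -0.025 to -0.005. The medians of the other lists with enough exons lay between the 4.88th and the 96.8th percentile. Ribosomal protein genes had 2 falls and 2 rises in 49 exons, the same adjusted over the list alone. The falls were in RPL34 (0.20 to 0.02) and RPS3 (0.52 to 0.40). Both rises were in RPL17, which went from 0.11 to 0.43 at a 98-nt 5' UTR exon. An 88-nt form of that exon overlaps it and had the same exclusion reads.

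The exons that fell in siSNRPA1 had a median length of 102 nt, against 123 nt for tested exons that did not pass, below all 10000 random sets of like depth. Their median GC content was 47.9% against 50% (0.01st percentile), and 61.1% lay within coding sequence against 45.1% (100th percentile). Upstream introns had a median of 2259 nt (97.7th percentile) and downstream introns of 1957 nt (19.7th percentile). Exons that rose had a median length of 125 nt (94.2nd percentile), and 51.1% of them also lay within coding sequence (99.9th percentile). The random sets were matched on depth but not on inclusion level, to which the rule for passing is tied.

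These calls rest on a two-sided Fisher's exact test per exon on the informative reads, with Benjamini-Hochberg adjustment, a difference in the authors' inclusion level of at least 0.1 and equal direction of both. The test compares the reads of 2 pools, not the conditions, and has no replicate check. Of the 1097 passing exons 75.4% had lower inclusion (95% Wilson interval 72.8 to 77.8%, counting error only). The count fell to 711 with at least 50 informative reads, 554 at a difference of at least 0.2, 416 with 1 exon per gene, 361 with reads thinned to the smallest pool and 291 with read counts divided by 2. With inclusion taken as the share of inclusion reads, PCID2, TANC1, THADA, DDX39B, SF1, DDX42, ITGA6 and RPS3 no longer passed, and with a minimum of 10 informative reads DDX39B had an adjusted p of 0.0507. The authors' deposited Bayes factors for LIMCH1 (3.91), EYA3 (5.65) and RPL34 (9.43) were under 10.

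**Figure D2:**
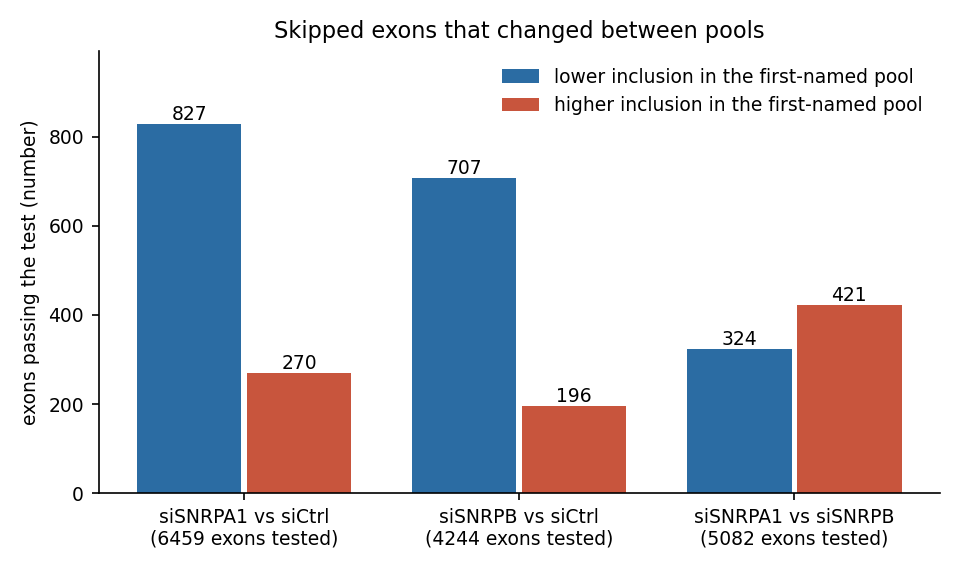
Number of exons that passed the test (vertical axis) with lower and higher inclusion in the first-named pool of each comparison, with the number of tested exons under each pair of bars. Against siCtrl, 827 exons fell and 270 rose in siSNRPA1, and 707 fell and 196 rose in siSNRPB.

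The second comparison set the siSNRPB pool against siCtrl. In the siSNRPB pool 707 exons of 583 genes fell and 196 exons of 181 genes rose, out of 4244 tested, with a median fall of 0.22 and a median rise of 0.20. Among exons with at least 50 informative reads in both pools, SNAP23, a SNARE protein of membrane fusion, had the largest fall. Its 159-nt coding exon (hg38 chromosome 15, 42528262 to 42528420) went from 0.82 (the authors' interval 0.77 to 0.87) to 0.22 (0.16 to 0.28). Inclusion reads made up 93.5% (95% Wilson interval 90.9 to 95.5%) of informative reads in siCtrl and 45.0% (35.9 to 54.3%) in siSNRPB, at an adjusted p of 1.16e-25 (Fisher's exact test).

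C1orf43 fell from 0.83 to 0.29 at a 54-nt coding exon, and MFSD1, a lysosomal membrane protein, from 0.97 to 0.46. CHN1, a GTPase-activating protein for Rac, fell from 0.94 to 0.44, SH3D19 from 0.95 to 0.45 and ARHGAP23 from 0.81 to 0.35. PUM2, an RNA-binding translational repressor, fell from 0.95 to 0.46 and the translation initiation factor EIF3K from 0.63 to 0.16. The largest rise at that depth was in NIPA2, a magnesium transporter, from 0.19 to 0.78 at a 113-nt exon of a noncoding transcript. The ribosomal protein RPL17 rose from 0.06 to 0.58 at an 88-nt 5' UTR exon, and DTYMK, the thymidylate kinase, from 0.53 to 0.96. The 60-nt coding exon of SPTAN1, the nonerythroid alpha spectrin (hg38 chromosome 9, 128592983 to 128593042), rose from 0.46 to 0.83, with 418 inclusion and 319 exclusion reads in siCtrl and 613 and 85 in siSNRPB. LAYN, a hyaluronan receptor, rose from 0.56 to 0.90 and MAPK7 (ERK5) from 0.19 to 0.52 at an 18-nt exon. PPHLN1 rose from 0.64 to 0.96, and D2HGDH from 0.42 to 0.79 at a 1065-nt 3' UTR exon.

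In the splicing machinery, 3 of 14 exons of the U2 snRNP and its partners rose and 2 fell (3 and 3 adjusted over the list alone). The 67-nt coding exons of U2AF1 and of its relative U2AF1L4, which bind the 3' splice site, rose from 0.38 to 0.70 and from 0.39 to 0.73, and SF1 fell from 0.52 to 0.42. Of 24 exons of Sm, LSm and other snRNP proteins 3 fell and 1 rose, also when adjusted over the list alone. SMN1 fell from 0.74 to 0.45, LSM14A fell from 0.94 to 0.72 and LSM2 rose from 0.71 to 0.94. SR proteins and related genes had 10 falls and 2 rises in 63 exons, the same adjusted over the list alone. SRSF10 fell from 0.87 to 0.29, RSRP1 from 0.67 to 0.10 and DYRK1A, a kinase, from 0.97 to 0.45. Of 79 exons of hnRNPs and other regulators 12 fell and 2 rose, with equal counts adjusted over the list alone, among them HNRNPR (0.95 to 0.60), CELF2 (0.89 to 0.59) and RBFOX2 (0.93 to 0.63).

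Cell cycle and mitosis genes had 15 falls and 4 rises in 59 exons (15 and 5 adjusted over the list alone). The share that passed, 32.2%, lay at the 98.0th percentile of random sets, and the median difference of -0.02 at the 24.2nd. That share had the highest percentile, and those of the other lists with enough exons ran from 15.2 to 92.4. AURKA, the mitotic Aurora A kinase, rose from 0.09 to 0.84 at a 195-nt 5' UTR exon, with 12 inclusion and 8 exclusion reads in siCtrl and 23 and 0 in siSNRPB. PLK4, the kinase of centriole duplication, fell from 0.94 to 0.56, and ASPM, a spindle pole protein, fell from 0.70 to 0.31 at a 4755-nt exon. Apoptosis genes had 8 falls and 0 rises in 30 exons, also when adjusted over the list alone. Among them were CASP4 (0.74 to 0.47) and BIRC5 (0.54 to 0.28), both at exons of noncoding transcripts, and BCL2L12 (0.94 to 0.70). DNA repair genes had 5 falls and 1 rise in 21 exons, the same adjusted over the list alone, with falls in ERCC1 (0.97 to 0.60), FANCI (0.94 to 0.61) and EXO1 (0.17 to 0.01). Chromatin regulators had 11 falls and 5 rises in 89 exons, with no change when adjusted over the list alone. CHD3 fell from 0.50 to 0.24, HDAC8 fell from 0.49 to 0.23 and TRIM33 rose from 0.66 to 0.95. Growth factor and kinase signalling had 13 falls and 3 rises in 85 exons (13 and 1 adjusted over the list alone), with falls in YAP1 (0.74 to 0.45) and MARK2 (0.59 to 0.34).

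Genes with exons known to switch in the epithelial-mesenchymal transition had 6 falls and 6 rises in 58 exons, also when adjusted over the list alone. ARHGEF11 fell from 0.63 to 0.14 and ARFGAP2 from 0.78 to 0.36, while MAP3K7 rose from 0.19 to 0.56. Cytoskeleton and adhesion genes had 9 falls and 9 rises in 84 exons (10 and 9 adjusted over the list alone). EPB41L1 rose from 0.38 to 0.85, DST, a cytoskeletal linker of the plakin family, rose from 0.43 to 0.81 at an 18-nt exon and NEXN rose from 0.14 to 0.51. The median difference of this list was 0, at the 97.9th percentile of random sets, and those of the remaining lists with enough exons lay between the 8.70th and the 97.1st percentile. Ribosomal protein genes had 1 fall, RPS24 from 0.25 to 0.13 at a 22-nt 3' UTR exon, and 2 rises in 40 exons, the same adjusted over the list alone. Both rises were in RPL17.

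Exons that fell in siSNRPB were flanked by longer introns than the tested exons that did not pass. The upstream median was 2748 nt against 1930 nt (99.99th percentile of random sets) and the downstream median 2557 nt against 2036 nt (99.6th percentile). The falling exons had median lengths of 114 nt (0.095th percentile) and a median GC content of 48.1% (0.305th percentile), and 62.4% lay within coding sequence (100th percentile). Exons that rose had a median length of 113 nt (2.81st percentile), against 124 nt for exons that did not pass, but the direction turned with inclusion as a read share (128 nt). Of the rising exons 54.1% lay within coding sequence (99.8th percentile). Their median downstream intron was 1536 nt (0.35th percentile), and 4.08% of these exons were at most 30 nt long, against 1.35% of exons that did not pass (99.5th percentile). The same test on the reads of 2 pools was used, with the same lack of a replicate check. Of the 903 passing exons 78.3% had lower inclusion (95% Wilson interval 75.5 to 80.9%). With the inclusion reads expected from unspliced RNA subtracted and inclusion as a read share, 67.7% of the passing exons were lower. That setting was chosen after the data were seen. The count fell to 539 with at least 50 informative reads, 512 at a difference of at least 0.2, 371 with 1 exon per gene and 300 with read counts divided by 2. With inclusion taken as the share of inclusion reads, ARHGAP23, DTYMK, SF1, LSM14A, HNRNPR, CASP4, BCL2L12, ASPM and FANCI no longer passed. The authors' deposited Bayes factors for SF1 (5.49) and DST (6.59) were under 10.

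The third comparison set the knockdown pools against each other. Of 5082 tested exons, 324 were lower and 421 higher in siSNRPA1 than in siSNRPB (745 in all, 14.7% of those tested). With the inclusion reads expected from unspliced RNA subtracted and inclusion as a read share, 381 were lower and 362 higher. The balance thus turned under these changes together. NIPA2 stood at 0.20 in siSNRPA1 and 0.78 in siSNRPB (adjusted p = 6.09e-10, Fisher's exact test), beside 0.19 in siCtrl. TRIM33, a ubiquitin ligase and chromatin regulator, stood at 0.44 and 0.95, NDUFB6, a subunit of respiratory complex I, at 0.39 and 0.88, and the kinase HIPK3 at 0.42 and 0.90. Higher in siSNRPA1 were CHN1 (0.95 and 0.44), MFSD1 (0.97 and 0.46), SH3D19 (0.86 and 0.45), WASHC2C, a subunit of the WASH complex of endosomes (0.93 and 0.47), and the 5' UTR exon of MSRB3, a methionine sulfoxide reductase (0.89 and 0.48). In this comparison too, the test on the reads of 2 pools had no replicate check. The count fell to 419 with at least 50 informative reads, 420 at a difference of at least 0.2, 434 with thinned reads, 301 with 1 exon per gene and 205 with read counts divided by 2.

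Among 3873 exons tested in both knockdowns against siCtrl, 434 fell in siSNRPA1 and 563 in siSNRPB, while 174 and 183 rose. Of these exons 236 fell in both, 53 rose in both and 4 passed in opposite directions. HARS2 (0.93 in siCtrl, 0.26 in siSNRPA1 and 0.29 in siSNRPB), RSRP1 (0.67, 0.10 and 0.10) and C1orf43 (0.83, 0.40 and 0.29) fell in both. Both comparisons use the same siCtrl pool, so these overlaps have no value for no change beside them. The differences correlated across exons at Pearson's r = 0.545 and Spearman's rho = 0.516, where exons are not independent replicates and no p-value is given. In read shares r was 0.542 with a covariance of 0.0103, beside a mean r of 0.480 (highest 0.528) and a mean covariance of 0.00157 (highest 0.00179) in 100 simulated pairs of unchanged pools. With the control reads split at random between the knockdowns, r was 0.425 and the covariance 0.00871, means of 20 splits. The 2 control libraries could not be parted, so a part of the excess that comes from the shared control was not ruled out.

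**Figure D3:**
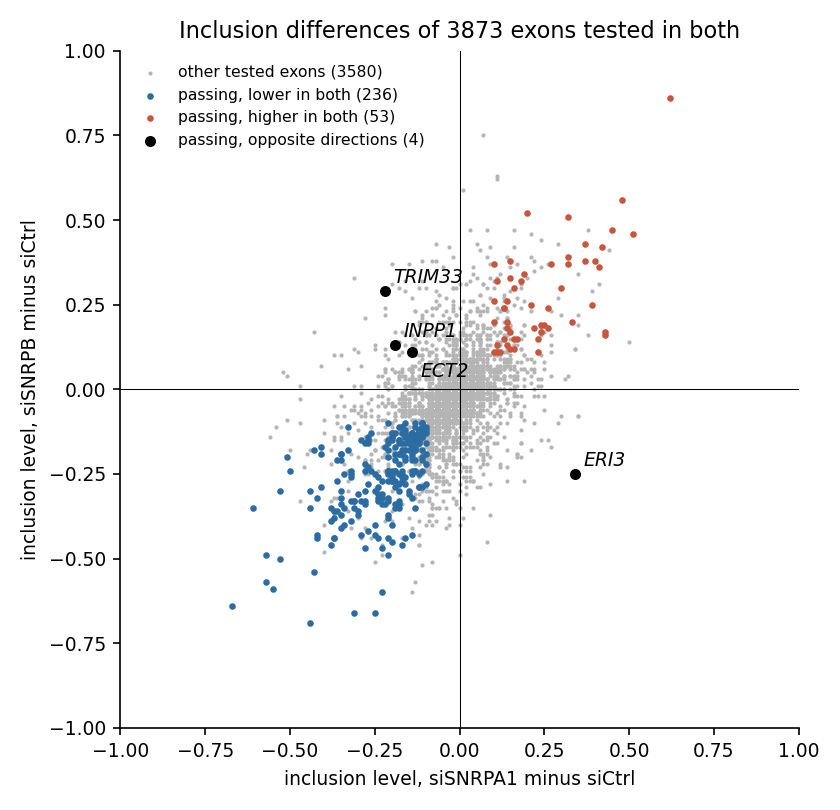
Difference in inclusion level from siCtrl in siSNRPA1 (horizontal axis) and siSNRPB (vertical axis) for the 3873 exons tested in both, 1 point per exon. Exons that passed in both are coloured by direction, 236 lower in both and 53 higher in both, and the 4 that passed in opposite directions are in black with their gene names.

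PLEC and ERRFI1 are named by the published study of these cells, so their values here are not independent evidence. PLEC encodes plectin, a linker of intermediate filaments, and its 3381-nt coding exon lies on hg38 chromosome 8, 143922504 to 143925884. The authors' inclusion level was 0.99 in siCtrl, 0.52 in siSNRPA1 and 1.00 in siSNRPB. The authors' deposited table gives a difference of -0.47 for siSNRPA1, with a Bayes factor of 1e+12. Exon-only reads numbered 80008, 55672 and 54786 in the siCtrl, siSNRPA1 and siSNRPB pools, and reads that skip the exon 51, 18 and 4. The share of inclusion reads was 99.94% (95% Wilson interval 99.92 to 99.95%) in siCtrl and 99.97% (99.95 to 99.98%) in siSNRPA1, so the reads and the inclusion level went in opposite directions and the exon did not pass. It did pass as lower in siSNRPA1 than in siSNRPB (adjusted p = 0.0209, Fisher's exact test), on 18 against 4 skipping reads, but not with inclusion as a read share. Coverage of the exon against its flanking exons was 50.6 exon reads per 100 flank reads in siCtrl, 24.3 in siSNRPA1 and 61.4 in siSNRPB. Microexons of 36 and 15 nt in PLEC stood at an inclusion level of 0.00 in all 3 pools and were not tested.

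ERRFI1, a feedback inhibitor of the EGF receptor, was measured at its 77-nt coding exon (hg38 chromosome 1, 8015308 to 8015384). The inclusion level was 0.67 in siCtrl, 0.20 in siSNRPA1 and 0.39 in siSNRPB. There were 269 inclusion and 0 exclusion reads in siCtrl, 112 and 2 in siSNRPA1, and 96 and 7 in siSNRPB. With so few exclusion reads the exon was not tested in siSNRPA1. In siSNRPB it passed as lower (adjusted p = 0.000805, Fisher's exact test), with inclusion reads at 93.2% (86.6 to 96.7%) against 100% (98.6 to 100%), but not with inclusion as a read share. A 93-nt form of the exon (8015308 to 8015400) had levels of 0.22, 0.10 and 0.14 and did not pass in siSNRPB, though it passed with inclusion as a read share. Of the exons of this pair of genes, 0 of 1 tested exon passed in siSNRPA1 and 1 of 3 in siSNRPB, also when adjusted over the list alone. Exon reads per 100 flank reads were 1.81, 0.543 and 1.11 in siCtrl, siSNRPA1 and siSNRPB.

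**Figure D4:**
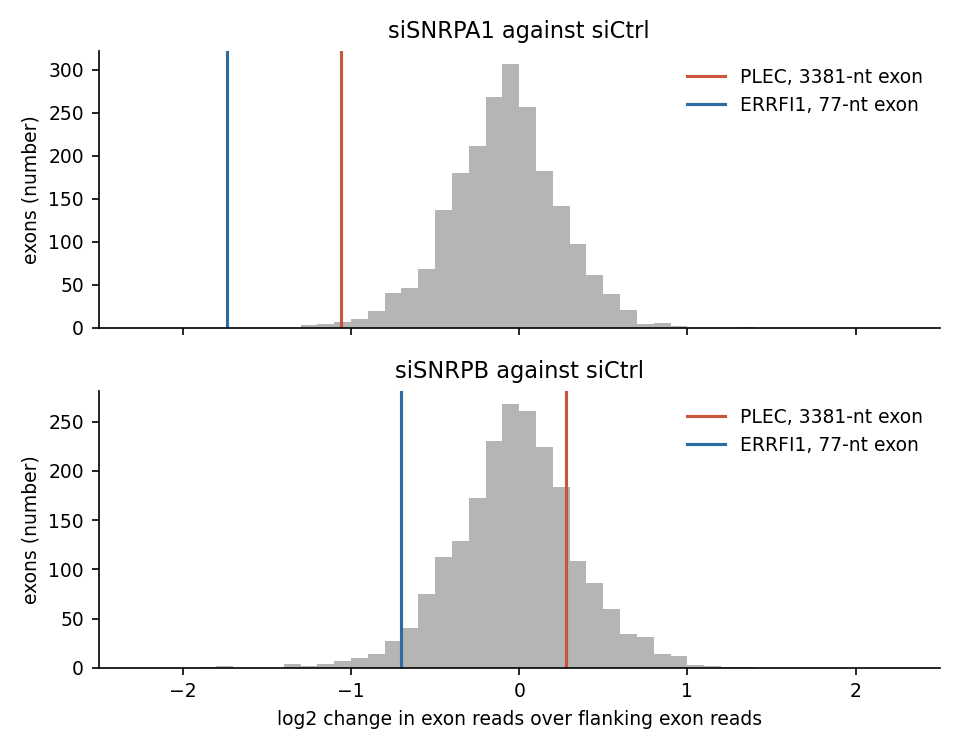
Number of exons (vertical axis) by the log2 change in exon reads over flanking exon reads (horizontal axis, bins of 0.1) in siSNRPA1 (top) and siSNRPB (bottom) against siCtrl, for 2119 exons with at most 1% exclusion reads in every pool. Lines mark the PLEC exon, at -1.06 and 0.28, and the ERRFI1 exon, at -1.74 and -0.70.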

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

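The tests of differences between libraries and of uneven coverage, and the subtraction of unspliced reads, were chosen only after the results were seen, and the condition on GC content was added to the coverage test after its spread was known. The 4 exons that passed in opposite directions in the knockdowns also passed the direct test between the knockdown pools, which largely restates that selection on the same reads, so no p-value is given. TRIM33 (0.66 in siCtrl, 0.44 in siSNRPA1, 0.95 in siSNRPB) differed by -0.51, siSNRPA1 minus siSNRPB. ERI3, an exoribonuclease (0.38, 0.72, 0.13), differed by 0.59. INPP1, an inositol phosphatase (0.32, 0.13, 0.45), differed by -0.32. ECT2, an exchange factor of cytokinesis (0.70, 0.56, 0.81), differed by -0.25. These are differences between reads of pools, with no replicate.

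The authors' deposited table held calls without skipping reads, a signal in values the comparisons above do not use. At a Bayes factor of at least 10 and a difference of at least 0.2, the authors' deposited table gave 2150 exons for siSNRPA1 and 2131 for siSNRPB, of which 972 (45.2%) and 967 (45.4%) had no exclusion read in either pool. Of these exons, 622 and 499 had reads enough for the test here, and 473 and 432 passed it.

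For these calls, skipping of the exon and uneven coverage were weighed. If skipping were the cause, calls with lower inclusion that did not pass on reads should hold the exclusion reads their inclusion level implies, but the ratio of their median observed over expected reads to that of exons that passed was 0, which does not match skipping; the calls are partly chosen for a lack of such reads, yet among all lower calls with at least 10 expected, 60.5% and 64.7% held under 0.2 of them. For PLEC, 18 exclusion reads were seen in siSNRPA1 where the inclusion level implies 1027 from flank reads or 1020 from inclusion reads, and for ERRFI1 2 where it implies 393 or 211. The log2 change of exon over flanking reads spread at least 2.38 times its counting error among exons with almost no skipping, but had a Spearman correlation of only -0.0609 and 0.0504 with exon GC content, so whether uneven coverage is the cause cannot be told. Other transcript ends or starts may give the same ratio, as a biological explanation that was not tested.

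Lower calls outnumbered higher ones in both knockdowns, 75.4% and 78.3%. After subtraction of expected unspliced reads, with inclusion as a read share, the percentages were 70.5 in siSNRPA1 and 67.7 in siSNRPB. Less unspliced RNA in the knockdown pools thus did not account for all of the skew under this subtraction. With the read share alone siSNRPA1 stood at 67.7, so the subtraction did not lower it there. The siSNRPB pool had fewer reads that fit neither isoform than siCtrl (a median of 68.8% against 79.9%). A part played by unspliced RNA was not ruled out there. For counting noise, simulated unchanged pools gave at most 0 calls. With independent reads the rule for passing nearly fixes that in advance, so the simulation cannot speak to the direction of the calls. Differences between libraries unrelated to the knockdowns cannot be told apart from the knockdowns, because 14.7% of tested exons passed between the knockdown pools too, and the common siCtrl pool alone could give a skew shared by both. Loss of spliceosome parts could biologically give more skipping, but no separate test of that was possible.

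The differences of the knockdown pools correlated across exons. Over random splits of the control reads the lowest covariance was 0.00848, above the highest of 0.00179 in simulated unchanged pools. Counting error of independent reads in the shared control thus does not account for the correlation. Both the splits and the simulation take reads as independent, and copies of a molecule can fall in both parts of a split. A larger counting error of the control was therefore not ruled out. The splits are of reads and not of libraries, so a peculiarity of the control pool beyond counting error may still contribute.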

How the results depend on the processing

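Subtraction of unspliced reads and the use of 1 exon per gene were chosen after seeing the data. The subtraction also took inclusion as a read share. No paired analysis was possible because each group has 1 file with values for the whole group, and leave-one-out was not run for the same reason. Alternatives by Bayes factor or the MISO filter were not run between the knockdowns, which the comparison files used here do not hold. With inclusion as a read share the PLEC exon in siSNRPA1, which did not pass, turned from -0.47 to 0.000314. Of 109 passing results for named exons over the 3 comparisons, 90 still passed with the read share, 108 with at least 10 reads, and 77 with at least 50, where the other 32 had too few reads to be tested. The number of passing exons was 1097 in siSNRPA1, 903 in siSNRPB and 745 between the knockdowns. In that order it was 711, 539 and 419 with at least 50 reads, 554, 512 and 420 at a difference of 0.2, 291, 300 and 205 with reads divided by 2, and 416, 371 and 301 with 1 exon per gene; these settings keep fewer exons or fewer reads by construction. Between the knockdowns the balance of 324 lower and 421 higher turned to 381 and 362 with unspliced reads subtracted and inclusion as a read share. The cause was not tested. Thinned reads gave 361 in siSNRPA1 and 434 between the knockdowns. Under the other settings the counts stayed within 1.5 times, 992 to 1512 in siSNRPA1 and 650 to 1206 in siSNRPB, but the exons were partly others: 473 of 1039 and 432 of 993 were shared with the MISO filter, 826 of 1243 and 698 of 1024 with the read share, and 650 of 992 and 582 of 823 with unspliced reads subtracted. The percent with lower inclusion in siSNRPA1, 75.4, was 78.5 with at least 50 reads, 72.4 at a difference of 0.05, 79.4 at 0.2, 79.5 with the Bayes factor, 67.7 with inclusion as a read share, 81.1 with reads divided by 2, 80.3 with thinned reads, 70.5 with unspliced reads subtracted and 78.6 with 1 exon per gene. In siSNRPB, 78.3, it was 73.4 with the MISO filter, 74.5 with the read share, 82.3 with reads divided by 2, 67.7 with unspliced reads subtracted and 80.9 with 1 exon per gene; the cause was not tested. The correlation of the knockdowns, 0.545, was 0.425 with the control reads split and 0.597 over passing exons only. With inclusion as a read share, the median difference was -0.0410 for Sm and LSm proteins in siSNRPB, -0.0402 and -0.0388 for SR proteins in siSNRPA1 and siSNRPB, 0.0108 for genes of the epithelial-mesenchymal transition in siSNRPA1, and -0.00190 and -0.000245 for ribosomal proteins in siSNRPA1 and siSNRPB; the share of lengths that are a multiple of 3 among falling exons in siSNRPA1 was 43.9%, and the median length of rising exons in siSNRPB 128 nt. With at least 50 reads the median GC content was 52.3% for rising exons in siSNRPA1 and 47.0% for falling exons in siSNRPB, and the share of rising exons in siSNRPB with a length that is a multiple of 3 was 59.6%; the cause was not tested. Depth limits which exons could be tested and which changes of 0.2 were found.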

Other observations

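The exons described here were chosen after their values were seen, as those with the largest difference that passed in both knockdowns. HMGCS1, an enzyme of cholesterol synthesis, fell at a 59-nt 5' UTR exon, from 0.85 in siCtrl to 0.30 in siSNRPA1 and 0.26 in siSNRPB. SLC7A2, a transporter of cationic amino acids, fell at a 46-nt 5' UTR exon (0.97, 0.40 and 0.48), and EXO5, an exonuclease, at a 58-nt 5' UTR exon (0.94, 0.52 and 0.50). SH2B1, an adaptor of receptor signalling, fell at a 100-nt exon (0.93, 0.49 and 0.24), and AP1B1, a clathrin adaptor subunit, at a 9-nt coding exon (0.62, 0.20 and 0.19). PCMTD1 rose at a 192-nt exon of a noncoding transcript (0.08, 0.70 and 0.94), and RAB11FIP3, an effector of recycling endosomes, at a 135-nt exon (0.29, 0.77 and 0.85). HDLBP, an RNA-binding protein, rose at a 125-nt 5' UTR exon (0.14, 0.59 and 0.61), EPSTI1 at a 59-nt exon (0.43, 0.94 and 0.89) and SLC30A5, a zinc transporter, at a 129-nt exon (0.52, 0.94 and 0.94).

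Some genes had several falling or rising exons, where forms of an exon with another start or end are counted apart. At least 2 exons fell in 123 genes in siSNRPA1 and in 107 genes in siSNRPB, and at least 3 in 18 and 15 genes. DAG1, or dystroglycan, had at least 4 falling exons in each knockdown and TROVE2, an RNA-binding protein, in siSNRPA1, while SPG7, a mitochondrial protease, had at least 4 rising exons in siSNRPA1. Neighbouring exons and overlapping forms of an exon can share exclusion reads. These counts are thus not of independent events, nor always of separate exons.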
